A study of Mus musculus with 12 samples.

How the data were processed

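RNA of mouse bone-marrow-derived macrophages, wild-type (WT) or lacking Alpk1 (KO), was sequenced after 4 h with PBS or 100 µM ADP-Hep, in 12 libraries that form 4 groups of 3. Per the labels' protocols, libraries were made from total RNA with a stranded mRNA kit. The authors deposited one table of whole-number read counts per gene, not normalized. Per the submitters' processing notes, the tools were FastQC, Trim Galore, STAR, featureCounts, RSEM and DESeq2 and the builds named were mm10 and hg38. Which of these tools made the counts, their versions, the annotation release and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore have been split or shared in ways that these counts do not show.

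Columns were assigned to groups by name. Of the KO ADP-Hep columns, 1 carried a number that matched no label; it was kept in its group with no replicate number. No per-sample column was left unassigned. All 37542 identifiers used were found in the GENCODE mouse release 21 annotation of mm10, 37363 of them with the same symbol, and coordinates are from there.

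The alignment of rows was checked by correlating mean log2(count + 1) of WT and KO libraries along the table. From one row on, the KO columns sat 1 row below the identifiers. The rows above it were used, less a margin of 100 rows, and 19206 rows were not used. In 20 simulated slips the method placed the break within 3 rows of its true place. This choice was made after the data were seen. One gene, ENSMUSG00000119584, lay in the rows not used and took 14.4 to 28.4% of a library's counts. Total counts per library ran from 16110654 to 31333973, and the rows used held 71.3 to 85.2% of them.

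Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Libraries were scaled by TMM, genes were kept by filterByExpr, which left 12261, and 1 quasi-likelihood model with robust estimation was fitted to all 4 group means. It gave 5 comparisons: ADP-Hep against PBS in WT cells, the same in KO cells, the difference between these responses (interaction), and KO against WT cells under each treatment. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 4.81%. Between replicates of a group, chi-square per degree of freedom of the counts was 2.00 to 10.9, so over all genes together no pair matched within sampling noise. Genes with very high counts can weigh most in this sum, so it does not describe a typical gene. The 44 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry; 39 lists had enough tested members. The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined.

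By that rule the text names Alpk1 first. In each comparison it then takes from the 10 largest increases and 10 largest decreases among called genes with at least 5 CPM in the higher group, no overlap between the libraries compared and a gene name. From each list it takes up to 4 called members with the smallest p, or values of the 2 most abundant where none was called, and any ALPK1 pathway member. A count of 0 over a group was set to a floor of 3 counts for a lower bound of the fold, and counts of 1 to 3 were given a 95% counting interval.

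On simulated data with 200 genes changed, the model recovered 51% of genes changed 1.2-fold, 75% at 1.5-fold, 91.8% at 2-fold and 100% at 4-fold for the WT response, with 7 unchanged genes called among 12099 tested. For the KO response these were 46%, 79.6%, 92% and 100%, with 12 unchanged genes called among 12089. For the interaction, among 12099 genes, 22.45% were recovered at 1.2-fold, 58.3% at 1.5-fold, 87.8% at 2-fold and 93.9% at 4-fold, with 8 unchanged genes called. For KO against WT under PBS, among 12089 genes, these were 36%, 79.6%, 95.9% and 97.9%, with 8 unchanged genes called. For KO against WT under ADP-Hep, among 12099 genes, they were 49%, 77.1%, 95.9% and 100%, with 11 unchanged genes called. These shares are for 200 changed genes, and the p cut-off of the adjustment shifts where far more genes change. A list raised 1.5-fold in simulated WT responses was called by camera among 12102 genes, with 0 other lists of the 39 called. Genes were drawn independently there, whereas the estimated correlation of the real interferon-stimulated list was 0.529. The simulation therefore does not test false list calls where members move together.

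The other settings tried were DESeq2 size factors, library totals as the only scaling, DESeq2 1.42.0 with its Wald test, limma-voom, no filter beyond 1 count, at least 1 CPM in 3 libraries, no robust estimation, glmTreat against a 1.5-fold change, a replicate block, fits of only the groups compared, and each library left out in turn. Thinning to a common depth and both treatments of the rows not used were added after the data were seen. Summaries and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

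Results for some single genes are not reported here.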

Results

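RNA was measured in bone-marrow-derived macrophages (BMDMs), primary mouse cells grown from marrow for 7 days in L929-conditioned medium, a source of the growth factor that drives macrophage differentiation. The marrow came from wild-type mice (WT) and from mice lacking Alpk1 (KO). Alpk1 encodes the kinase that senses ADP-heptose (ADP-Hep), a sugar nucleotide made by Gram-negative bacteria during lipopolysaccharide synthesis, and signals through the adaptor TIFA to NF-kB. Cells received 100 µM ADP-Hep or PBS for 4 h, which gave 4 groups of 3 libraries. Total counts ran from 16110654 to 31333973 per library, of which 12307826 to 25742912 lay in the part of the table used here, and 12261 genes were tested. The first principal component of log2 CPM held 69.2% of the variance and set the WT ADP-Hep libraries (64.2 to 67.3) apart from all others (-28.9 to -17.4). Group levels are mean CPM, read counts scaled by library size, ± SD of the 3 libraries. Changes are log2 fold changes from edgeR's quasi-likelihood test ± SE. The test itself gives no SE. The value used is the absolute change divided by the square root of the test's F statistic, an approximation.

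In the lower part of the deposited table the KO columns did not line up with the gene identifiers. Across genes, mean log2 counts of WT and KO libraries had r = 0.995 in the 37542 rows used and r = 0.0429 in the rows below the break, where moving the KO columns up by 1 row gave r = 0.975. The comparisons therefore use the upper rows, which hold 21383 protein-coding genes, and leave out 19206 rows with 539 protein-coding genes. With all rows as deposited, KO against WT under PBS would have given 1632 genes higher and 1518 lower.

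**Figure D1:**
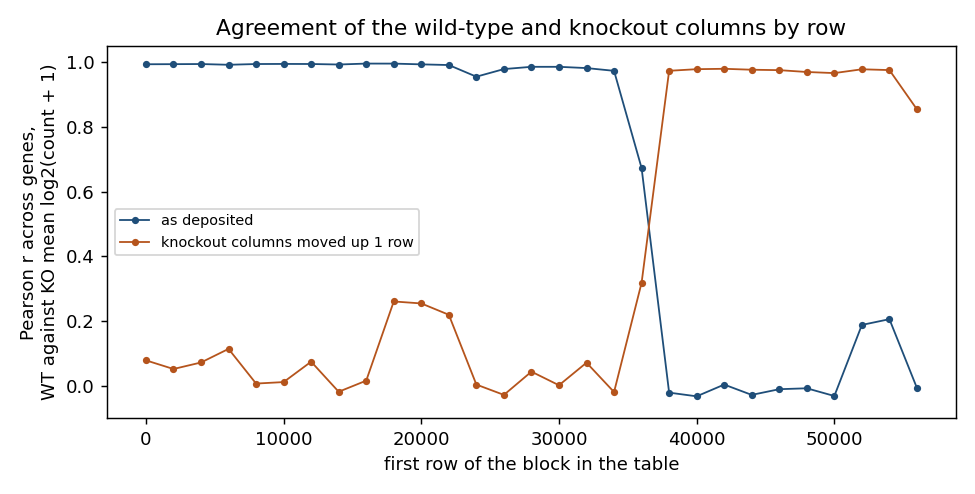
Pearson r across genes between wild-type and Alpk1 knockout mean log2(count + 1) (vertical axis) for successive blocks of rows of the deposited table (horizontal axis), as given and with the knockout columns moved up 1 row. As given, blocks wholly above the break reached at least 0.955 and blocks wholly below at most 0.206, while moving up gave at least 0.854 below it.

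Alpk1 (ENSMUSG00000028028; chromosome 3, 127670310 to 127780527, minus strand, mm10) was read first in every library. The WT PBS libraries held 30.1, 32.1 and 25.9 CPM and the WT ADP-Hep libraries 53.8, 55.3 and 52.3 CPM. The KO PBS libraries held 22.3, 20.3 and 21.3 CPM, and the KO ADP-Hep libraries 21.6, 19.2 and 22.4 CPM. Alpk1 mRNA thus rose with ADP-Hep in WT cells (0.89 ± 0.07, adjusted p = 3.1e-11), and no change was called in KO cells (0.00088 ± 0.08, adjusted p = 0.996). KO libraries lay below WT libraries under PBS (-0.45 ± 0.08, adjusted p = 0.00037) and under ADP-Hep (-1.34 ± 0.07, adjusted p = 1.5e-14). Reads over the gene remained in every KO library. The deleted part of the gene is not given in the labels, so a count over the whole gene does not check the genotype by its size.

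**Figure D2:**
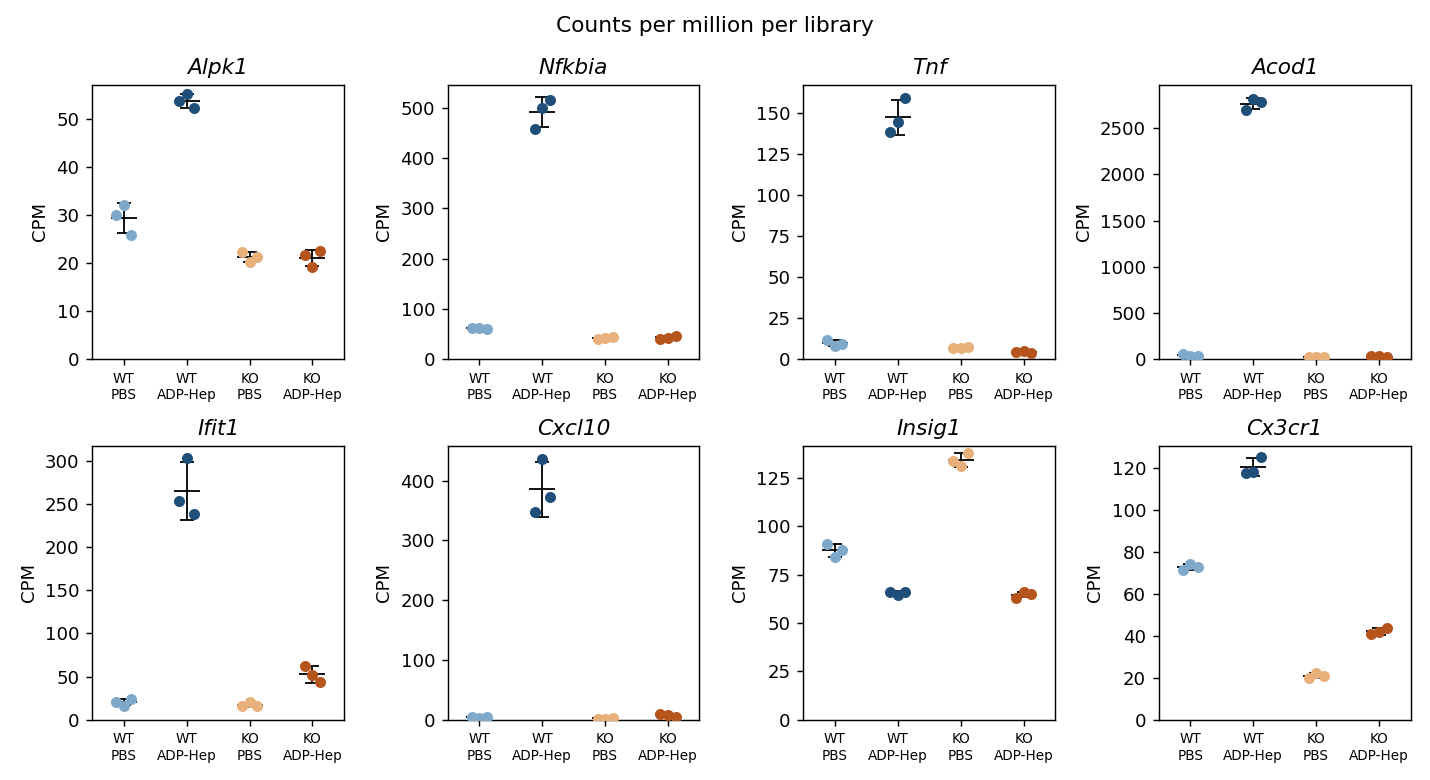
CPM (vertical axes, linear, from 0) of 8 genes in each of the 12 libraries, by genotype and treatment; points are libraries, horizontal marks group means and bars 1 SD (n = 3). Acod1 stood at 2767 CPM in WT ADP-Hep libraries and 26.5 CPM in KO ADP-Hep libraries, whereas Ifit1 reached 52.7 CPM in KO ADP-Hep libraries against 17 CPM in KO PBS libraries.

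The comparison of ADP-Hep with PBS in WT cells asked how macrophages with the receptor respond. ADP-Hep raised inflammatory mediators. Acod1, which makes itaconate (chromosome 14, 103046977 to 103056573), went from 40.8 ± 7.33 to 2767 ± 61.4 CPM (6.09 ± 0.13, adjusted p = 7.7e-13). Il1b, encoding the pyrogenic cytokine IL-1β, went from 0.404 ± 0.16 to 83.8 ± 3.36 CPM (7.70 ± 0.19). Il12b, a subunit of IL-12 and IL-23, had 0 counts over the 3 PBS libraries and 646 over the ADP-Hep libraries, at least 195-fold higher against a floor of 3 counts over the group. The neutrophil attractant Cxcl3 had 2 counts against 653, a ratio of 295 (95% counting interval 81.4 to 2443). Such floors and intervals cover counting error only. Other genes among the 10 with the largest increases were the interferon-induced chemokine Cxcl10 (6.54 ± 0.21), the cystine transporter Slc7a11 (6.19 ± 0.21), the inducible nitric oxide synthase Nos2 (6.08 ± 0.27), Serpinb2 (7.16 ± 0.25) and the class Ib histocompatibility gene H2-M2 (6.36 ± 0.20).

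Among NF-kB feedback and subunit genes, 19 of 20 tested members were higher in WT cells after ADP-Hep and 0 were lower, with a median log2 change of 1.95. They included the inhibitors Nfkbia (3.00 ± 0.06) and Nfkbie (4.19 ± 0.08) and the signalling adaptors Traf1 (5.45 ± 0.10) and Tnip3 (3.24 ± 0.05). The list moved up against other genes (camera adjusted p = 1.5e-12; adjusted p = 0.0154 with an estimated correlation). Of 16 inflammatory cytokines tested, 15 were higher and 1 lower, among them Tnf (3.92 ± 0.08) and the IL-1 receptor antagonist Il1rn (2.08 ± 0.06). The list median was 2.03, also with Il12b set at its bound (adjusted p = 0.0154 with an estimated correlation). Chemokines rose in 18 of 20 cases with none lower, such as Cxcl2 (5.50 ± 0.11) and Ccl3 (2.30 ± 0.07), and their call held with an estimated correlation (adjusted p = 0.00387). A list of nitric oxide, prostaglandin and itaconate enzymes and other effector genes (the enzyme list) gave 16 higher and 2 lower of 19. Among the other effector genes, the mitochondrial superoxide dismutase Sod2 (3.28 ± 0.05) and the acute-phase gene Saa3 (4.68 ± 0.07) rose. Inflammasome and cell death genes gave 17 higher and 4 lower of 24, including the inflammasome sensor Nlrp3 (3.51 ± 0.05), the lipopolysaccharide-binding caspase Casp4 (2.40 ± 0.07) and the death receptor Fas (2.58 ± 0.09). Both of these lists held with an estimated correlation (adjusted p = 0.0154 each). Adjusted over the list alone, the counts in these 5 lists were the same.

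All 37 tested type I interferon-stimulated genes were higher in WT cells after ADP-Hep, with a median of 1.93. Parp14 (2.56 ± 0.07), the guanylate-binding protein Gbp2 (3.10 ± 0.08), the immunity-related GTPase Igtp (1.93 ± 0.07) and the DNA sensor family member Ifi205 (5.88 ± 0.17) were among them. Camera with the preset correlation called the list (adjusted p = 9.6e-17), but not with the correlation estimated over its members (adjusted p = 0.203 with an estimated correlation). Pattern recognition receptors and adaptors split into 18 higher and 9 lower of 29. The C-type lectin Clec4e rose from 19.5 ± 0.547 to 965 ± 5.0 CPM, and Tlr2 (2.57 ± 0.05) and the scavenger receptor Marco (1.49 ± 0.04) also rose (list adjusted p = 0.216 with an estimated correlation). Immediate-early and AP-1 genes gave 17 higher and 2 lower of 27, with Fos at 2.82 ± 0.07 and Junb at 1.95 ± 0.05 (adjusted p = 0.232 with an estimated correlation). Antigen presentation and co-stimulation genes gave 18 higher and 1 lower of 23, led by p by the adhesion molecule Icam1 (3.22 ± 0.05) and the co-stimulatory receptor Cd40 (4.61 ± 0.11); the list lost its call in the stricter test (adjusted p = 0.116 with an estimated correlation). NRF2 targets gave 17 higher and 1 lower of 20, including the autophagy receptor Sqstm1 (1.53 ± 0.06), glutathione reductase Gsr (1.32 ± 0.07) and Nfe2l2 itself (0.90 ± 0.05), with adjusted p = 0.253 with an estimated correlation. Adjusted over the list alone, the antigen presentation list held 18 higher and 2 lower, and the other lists of this paragraph kept their counts.

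Genes of DNA replication fell. Of 22 S-phase genes tested, 0 were higher and 18 lower (0 and 19 adjusted over the list alone), with a median of -0.44, and the call held with an estimated correlation (adjusted p = 0.0463). The replication licensing genes Cdt1 (-1.90 ± 0.07), Cdc6 (-1.35 ± 0.13) and Mcm7 (-0.84 ± 0.06) were among them. Of 23 genes of G2 and M phase, 13 were lower and 0 higher, the same adjusted over the list alone, with the mitotic checkpoint gene Bub1b at -0.67 ± 0.05 (list adjusted p = 0.439 with an estimated correlation). Lysosome and phagocytosis genes gave 17 lower and 2 higher of 25 (19 and 3 adjusted over the list alone), including the efferocytosis receptor Mertk (-2.28 ± 0.06) and its ligand Gas6 (-1.34 ± 0.05), with adjusted p = 0.187 with an estimated correlation. The largest decreases among well expressed genes included the prostaglandin-degrading enzyme Hpgd (-4.16 ± 0.26), the chemokine receptor Cxcr4 (-3.57 ± 0.11), Frat2 (-4.10 ± 0.19), Rnf144b (-3.57 ± 0.09) and the transcription factor Sox4 (-3.49 ± 0.12). Sox4 was also 1 of 5 haematopoietic progenitor markers tested, of which 4 were lower and 0 higher, the same adjusted over the list alone, with a median of -0.65. That list did not pass camera (adjusted p = 0.0887) and passed fry (adjusted p = 8.9e-08). Within the ALPK1 pathway list, 10 of 13 components were higher and 2 lower, also adjusted over the list alone. Traf2 (1.30 ± 0.07) and Tifa (0.49 ± 0.05) rose and Tifab, which encodes a TIFA-related protein, fell (-0.94 ± 0.08; list adjusted p = 0.0888 with an estimated correlation).

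Over all genes, 3914 were higher and 3871 lower in WT cells after ADP-Hep (edgeR, Benjamini-Hochberg adjusted p under 0.05), 835 and 828 of them by at least 2-fold. The 3 libraries of one treatment lay wholly above or below those of the other for 8086 of the 12261 genes tested (65.95%), called or not, where chance gives 10%. Scaling by library totals alone put the median of all genes at -0.12, against -0.0058 with TMM, and gave 2990 higher and 4927 lower, so the even split of directions rests on the scaling. Against a change of at least 1.5-fold (edgeR's glmTreat), 1083 were higher and 1055 lower. Nothing in the labels says that the libraries of a group came from separate animals or cultures. The p-values in every comparison therefore measure the spread between these libraries, which may be technical.

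**Figure D3:**
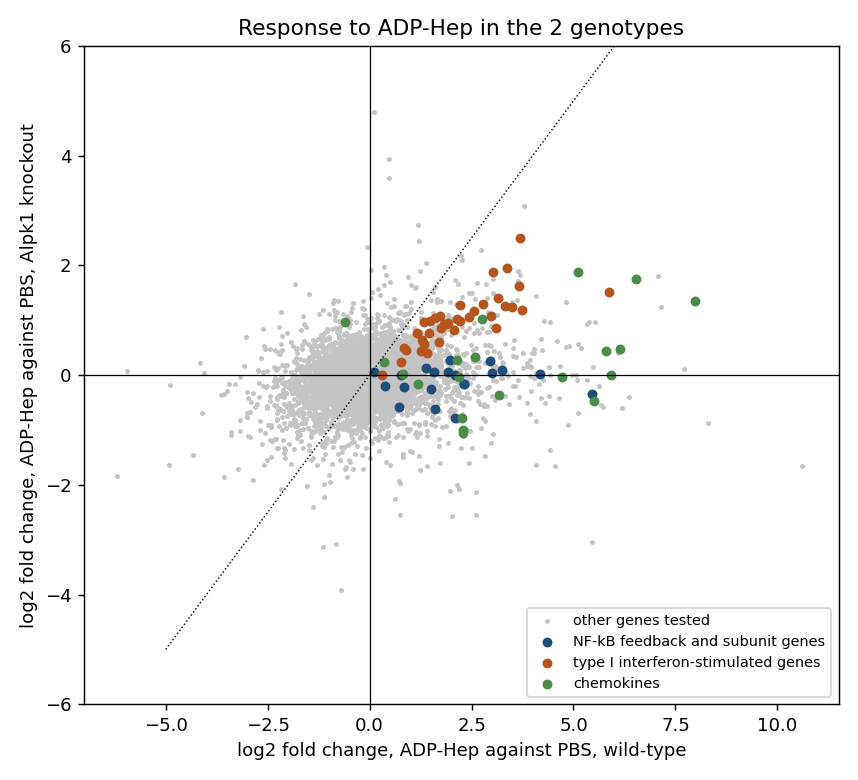
Log2 fold change with ADP-Hep in wild-type (horizontal) and Alpk1 knockout macrophages (vertical) for the 12261 genes tested; colours mark 3 fixed gene lists and the dotted line equal change. NF-kB feedback genes lie along the horizontal axis (list medians 1.95 and 0.00456), and interferon-stimulated genes lie above it (list medians 1.93 and 0.98).

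The same comparison in KO cells asked what ADP-Hep does without Alpk1. The inflammatory lists gave no call with camera. NF-kB feedback genes showed 2 higher and 7 lower of 20 (2 and 8 adjusted over the list alone). For this list camera gave adjusted p = 0.287, whereas fry called it lower (adjusted p = 0.0132). Nfkb2 stood at 0.26 ± 0.07, and Tnfaip2 (-0.79 ± 0.05) and Tnip1 (-0.62 ± 0.06) were lower. Inflammatory cytokines showed 3 higher and 2 lower of 16, the same adjusted over the list alone (camera adjusted p = 0.973). Tnf was lower (-0.71 ± 0.15, adjusted p = 0.00068), at 4.28 ± 0.397 CPM after ADP-Hep against 6.94 ± 0.498 CPM with PBS. Chemokines showed 5 higher and 4 lower of 20 (6 and 4 adjusted over the list alone; camera adjusted p = 0.723). Ccl3 fell to 11.4 ± 0.569 CPM (-1.0 ± 0.08) and the chemokine-binding receptor Ccrl2 to 4.92 ± 0.428 CPM (-1.06 ± 0.12).

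Interferon-stimulated genes were the exception. Of 37 tested, 35 were higher and 0 lower after ADP-Hep in KO cells, the same adjusted over the list alone, with a median of 0.98. The antiviral genes Ifit3b (2.50 ± 0.19), Ifit3 (1.87 ± 0.19), Ifit1 (1.62 ± 0.21) and Oasl1 (1.95 ± 0.28) and Cmpk2 (1.41 ± 0.21) rose, as did Parp14 (1.16 ± 0.07), Igtp (0.96 ± 0.08) and the RNA sensor Ddx58 (0.86 ± 0.08). Outside the list, the GTPase Iigp1 (2.27 ± 0.23) and Rtp4 (1.5 ± 0.10) also rose. The level of Cxcl10 stayed low, reaching 7.57 ± 2.25 CPM from 2.31 ± 0.720 CPM (1.76 ± 0.37, adjusted p = 0.0067). Reads of Ifit3 and Ifit3b, which are close copies, could not be told apart with certainty. Camera called the list with the preset correlation (adjusted p = 1.3e-22) and not otherwise (adjusted p = 0.285 with an estimated correlation).

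Other lists moved down in KO cells. Of 21 genes of cholesterol synthesis and uptake, 0 were higher and 11 lower (0 and 13 adjusted over the list alone), including Insig1 (-1.06 ± 0.05) and Hmgcs1 (-0.42 ± 0.04) (adjusted p = 0.222 with an estimated correlation). The fall started from KO PBS libraries that lay above WT PBS libraries. Mean log2 CPM over the cholesterol list was 6.03 to 6.122 in KO PBS, 5.778 to 5.849 in KO ADP-Hep and 5.662 to 5.716 in WT PBS libraries. Insig1 did end below WT PBS, at 63.0 to 65.8 against 84.0 to 91.0 CPM. Lysosome genes gave 17 lower and 0 higher of 25 (21 and 0 adjusted over the list alone), for example the galactosidase Gla (-0.35 ± 0.04) and Mertk (-0.40 ± 0.06). Genes of the unfolded protein response gave 8 lower and 0 higher of 20 (9 and 0 adjusted over the list alone), among them Atf4 (-0.93 ± 0.09), Herpud1 (-0.44 ± 0.06) and Ddit3 (-0.79 ± 0.14). Each of these lists had adjusted p = 0.222 with an estimated correlation. Immediate-early genes gave 11 lower and 0 higher of 27, also adjusted over the list alone, with Jun at -0.80 ± 0.06 and Klf6 at -0.57 ± 0.05 (adjusted p = 0.589 with an estimated correlation). Neutrophil markers moved with these lists: 5 of 11 were lower and 0 higher (6 and 0 adjusted over the list alone), Ngp by -0.61 ± 0.08 and Csf3r by -0.61 ± 0.07 (adjusted p = 0.328 with an estimated correlation). The folliculin-binding gene Fnip2 (-1.54 ± 0.05), Cxcr4 (-1.85 ± 0.09), the phosphatase gene Dusp4 (-2.57 ± 0.25) and Ppp1r15a (-1.65 ± 0.21) were among the 10 largest decreases, and the fractalkine receptor Cx3cr1 rose from 21 ± 1.15 to 42.2 ± 1.51 CPM (1.00 ± 0.06).

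In total 1678 genes were higher and 1870 lower in KO cells after ADP-Hep, 94 and 135 of them by at least 2-fold. Libraries of the 2 treatments did not overlap for 5156 of all genes tested (42.05%), against 10% by chance. Tested against a change of at least 1.5-fold (glmTreat), 54 were higher and 113 lower. Scaling by library totals gave 2360 higher and 1483 lower. Leaving out KO ADP-Hep replicate 1 left 1179 higher and 1406 lower. In mitochondrially encoded mRNAs that library had a mean log2 CPM of 9.084, against 9.775 and 9.599 in the other KO ADP-Hep libraries. Whether this bears on the KO calls was not tested.

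The interaction compared the response in WT with that in KO cells, the part of the response that differed between genotypes. Whether WT and KO mice were littermates is not given, so this part cannot be assigned to Alpk1 alone. Of the 18 lists called, chemokines, cytokines and NF-kB feedback genes had the highest medians (3.27, 2.10 and 1.98), followed by the enzyme list (1.94). Of 20 NF-kB feedback genes, 19 responded more strongly upward in WT cells and 0 less (adjusted p = 0.0101 with an estimated correlation), for example Nfkbia (2.96 ± 0.09), Tnip3 (3.15 ± 0.09) and Tnfaip2 (2.89 ± 0.07). Cytokines gave 15 and 0 of 16, with Tnf at 4.63 ± 0.18 and Il1b at 7.59 ± 0.77 (adjusted p = 0.0135 with an estimated correlation). Chemokines gave 15 and 0 of 20 (16 and 1 adjusted over the list alone), with Cxcl2 at 5.96 ± 0.36, Ccl3 at 3.30 ± 0.11 and Ccl9 at 1.86 ± 0.07 (adjusted p = 0.00307 with an estimated correlation). The enzyme list gave 15 and 3 of 19, with Sod2 at 3.06 ± 0.07 and Saa3 at 4.51 ± 0.10 (adjusted p = 0.0101 with an estimated correlation). Nlrp3 differed by 3.16 ± 0.08, Icam1 by 3.26 ± 0.08 and Clec4e by 5.83 ± 0.13. Ptgs2, encoding cyclooxygenase-2, differed by 8.51 ± 0.96, and its KO PBS libraries spread over 2.91, 0.659 and 5.0 CPM. These lay above its WT PBS libraries (0.425 to 0.586 CPM), and its KO ADP-Hep libraries held 8, 1 and 9 counts. The Ptgs2 interaction therefore includes a difference under PBS and rests in part on a group with few counts. Slc7a11 (6.80 ± 0.34), H2-M2 (6.76 ± 0.88) and the adenosine receptor Adora2a (6.30 ± 0.68) also stood among the 10 largest. Adjusted over the list alone, the counts of the NF-kB, cytokine and enzyme lists were the same. Alpk1 itself differed by 0.89 ± 0.11.

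Interferon-stimulated genes rose in both genotypes and rose further in WT cells: 34 of 37 had a positive interaction and 0 a negative one (36 and 0 adjusted over the list alone), with a median of 1.01 (adjusted p = 0.250 with an estimated correlation). Gbp2 differed by 2.24 ± 0.12 and Parp14 by 1.40 ± 0.10. Immediate-early genes gave 20 positive and 2 negative of 27 (21 and 2 adjusted over the list alone), with Fos at 2.60 ± 0.12 and Junb at 2.07 ± 0.08 (adjusted p = 0.126 with an estimated correlation). Cholesterol genes gave 16 positive and 1 negative of 21, the same adjusted over the list alone. The cholesterol list had adjusted p = 0.0898 with an estimated correlation. Its median in KO against WT cells was 0.38 under PBS and -0.02 under ADP-Hep, so its interaction includes the difference under PBS. Sqstm1 (2.29 ± 0.09) and Ppp1r15a (3.07 ± 0.27) rose in WT cells and fell in KO cells. S-phase genes gave 17 negative and 0 positive of 22 (19 and 0 adjusted over the list alone), with Cdt1 at -1.25 ± 0.10, Cdc6 at -1.53 ± 0.17 and Mcm7 at -0.90 ± 0.09, and held with an estimated correlation (adjusted p = 0.0209). Of single genes that fell in WT cells, Hpgd (-4.38 ± 0.32), Rnf144b (-3.23 ± 0.12) and the peroxisomal transporter Abcd2 (-3.23 ± 0.11) had negative interactions. In the pathway list Traf2 (1.31 ± 0.11) and Tifab (-1.23 ± 0.10) differed.

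The interaction was positive for 3018 genes and negative for 3053; scaling by library totals, which put the median of all genes at -0.16 against -0.0099, gave 2020 and 4507, and glmTreat against 1.5-fold 820 and 706. Of the 835 genes at least 2-fold higher in WT cells, 726 (87.0%) had an interaction in that direction, and the median log2 change of all 835 in KO cells was 0.12. Of the 828 at least 2-fold lower, 701 (84.7%) did, with a median of -0.22 in KO cells. The interaction uses the WT libraries that picked these genes, so the selection favours such shares. Over all genes tested, 49.51% had an interaction called in either direction. The KO medians come from libraries not used in the selection. Across genes, which are not independent replicates, the WT and KO changes had Pearson r = 0.235 and Spearman rho = 0.248; the 2 responses share no libraries. Both called 915 genes higher, where independent lists would share 535.7, and both called 1075 lower, against 590.4. Opposite calls covered 413 genes higher in WT and lower in KO cells, against 596.9, and 334 the other way, against 529.8.

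**Figure D4:**
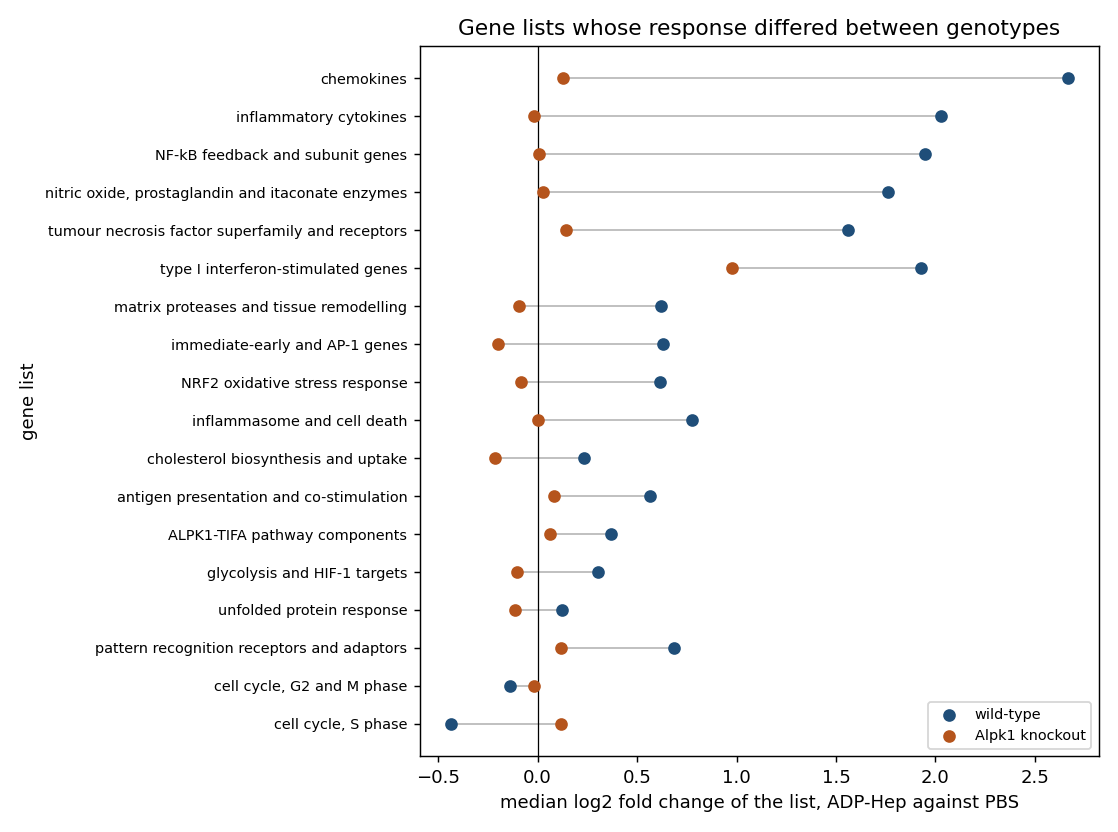
Median log2 fold change with ADP-Hep (horizontal axis) in wild-type and Alpk1 knockout cells for the 18 gene lists whose response differed between genotypes by camera with the preset correlation, ordered by the interaction. The interferon-stimulated list has the highest knockout median of the 18 at 0.98, against 1.93 in wild-type cells. With an estimated correlation 6 of the 18 kept their call, and the interferon-stimulated list did not (adjusted p = 0.250).

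Under PBS, KO and WT cells were compared to see what differed before any agonist. The labels name C57BL/6N and the design text C57BL/6, and whether WT and KO mice were littermates is not given in the sources used here. These differences therefore compare 2 sets of mice and cannot be assigned to Alpk1 alone. Genes of cholesterol synthesis and uptake were higher in KO cells: 17 of 21 higher and 0 lower (19 and 0 adjusted over the list alone), median 0.38, a call that held with an estimated correlation (adjusted p = 0.0129). The sterol sensor Insig1 (0.61 ± 0.05) and the enzymes Sc5d (0.58 ± 0.05), Fdft1 (0.60 ± 0.06) and Cyp51 (0.50 ± 0.05) were among them. On the list of LXR targets and lipid efflux, Scd2 was higher, at 213 ± 11.1 against 81.7 ± 3.27 CPM (1.38 ± 0.05). Fasn on that list was higher by 0.68 ± 0.06, whereas the lipid droplet gene Plin2 was lower (-0.56 ± 0.05). That list gave 7 higher and 1 lower of 18 (8 and 1 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation). Targets of p53 gave 7 higher and 0 lower of 15 (9 and 0 adjusted over the list alone; adjusted p = 0.0471 with an estimated correlation), with small changes in Cdkn1a (0.31 ± 0.05), Sesn1 (0.27 ± 0.05) and Sesn2 (0.39 ± 0.07).

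NF-kB feedback genes were lower in KO cells without agonist: 9 of 20 lower and 1 higher (12 and 2 adjusted over the list alone), with Tnip3 at -0.77 ± 0.07, Relb at -0.64 ± 0.07 and Nfkbia at -0.55 ± 0.06 (adjusted p = 0.134 with an estimated correlation). The chaperones Hspa5 (-0.41 ± 0.05) and Manf (-0.41 ± 0.05) were lower, in a list of the unfolded protein response with 11 lower and 2 higher of 20 (11 and 5 adjusted over the list alone; adjusted p = 0.300 with an estimated correlation). Interferon-stimulated genes gave 1 higher and 2 lower of 37, the same adjusted over the list alone, with a median of -0.16 (adjusted p = 0.659 with an estimated correlation). G2 and M phase genes gave 9 lower and 0 higher of 23 (14 and 0 adjusted over the list alone), Tpx2 by -0.26 ± 0.05 (adjusted p = 0.300 with an estimated correlation). NRF2 targets gave 8 higher and 0 lower of 20 (12 and 0 adjusted over the list alone), with the glutathione synthesis gene Gclm at 0.62 ± 0.07 (adjusted p = 0.418 with an estimated correlation). Gclm lies within 10 Mb of Alpk1 on chromosome 3, so for this gene an effect of DNA near Alpk1 cannot be told apart from the genotype. Of single genes, arginase Arg1 was at 1.46 ± 0.154 against 7.22 ± 1.59 CPM (-2.26 ± 0.20) and Cx3cr1 at 21 ± 1.15 against 72.9 ± 1.52 CPM (-1.79 ± 0.06); Cav1 (-1.46 ± 0.14), Rab4a (-1.26 ± 0.13) and the collagenase Mmp13 (-1.12 ± 0.14) were also lower. Higher in KO cells were Eps8l1 (1.83 ± 0.17), Saa3 (1.63 ± 0.08), the endothelin receptor Ednrb (1.36 ± 0.09), the macrophage survival gene Cd5l (1.35 ± 0.06) and the dicarboxylate transporter Slc13a3 (1.26 ± 0.08). The largest increase, Slco4a1 (2.85 ± 0.58, adjusted p = 0.0164), rested on KO PBS libraries at 39.9, 10.4 and 50.4 CPM, and its call was lost with glmTreat (adjusted p = 0.358), without KO PBS replicate 1 (adjusted p = 0.0598), without WT PBS replicate 1 (0.055) or 2 (0.0581), or in a fit of the PBS groups alone (0.123).

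Under PBS 683 genes were higher and 714 lower in KO cells, 54 and 38 of them by at least 2-fold, and libraries did not overlap for 3393 of all 12261 genes tested (27.67%), where chance gives 10%. Leaving out KO PBS replicate 1 left 438 higher and 391 lower. That library was also low in mitochondrially encoded mRNAs, with a mean log2 CPM over the list of 8.464 against 9.65 and 9.359 in the other KO PBS libraries and 9.42 to 9.507 in WT PBS libraries. Whether this bears on the calls was not tested. With all libraries, 15 higher and 16 lower passed against a change of at least 1.5-fold with glmTreat.

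**Figure D5:**
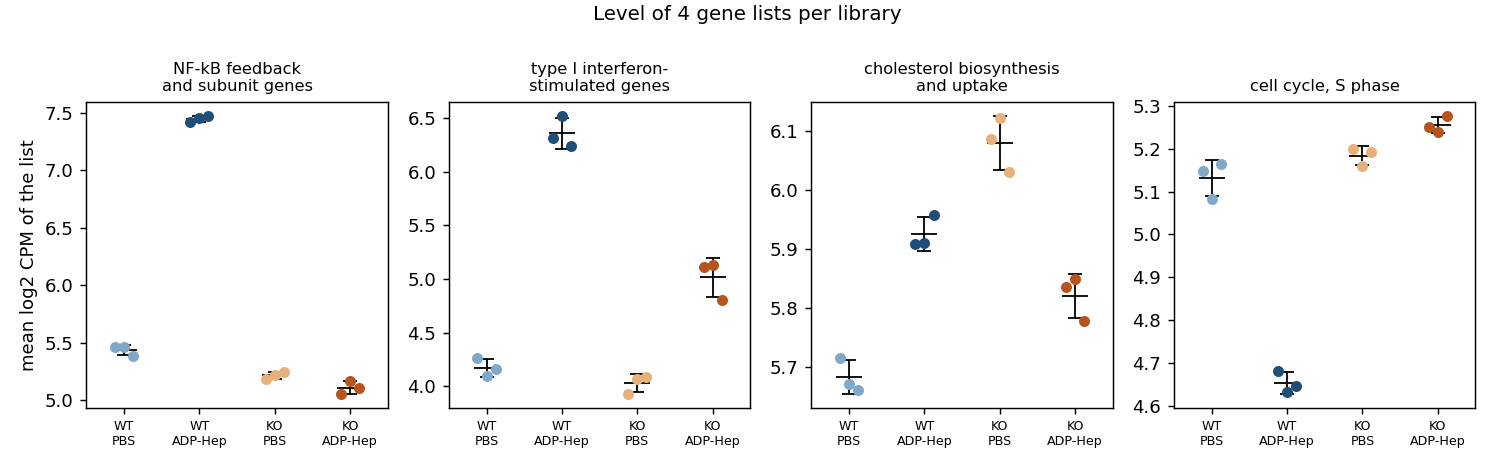
Mean log2 CPM over the members of 4 gene lists (vertical axes, which do not start at 0) in each library, by genotype and treatment, with group means and 1 SD (n = 3). The NF-kB list rose in the WT ADP-Hep group alone, the interferon list rose in both genotypes, and the cholesterol list was highest in the KO PBS libraries.

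Under ADP-Hep, KO cells were compared with WT cells given the same agonist. KO cells had far less of the inflammatory transcripts: all 20 NF-kB feedback genes were lower (median -2.25; adjusted p = 0.0136 with an estimated correlation), with Traf1 at 1.88 ± 0.485 against 102 ± 3.94 CPM (-5.83 ± 0.10), Tnip3 at -3.91 ± 0.06 and Nfkbia at -3.52 ± 0.06. Cytokines gave 14 lower and 0 higher of 16 (adjusted p = 0.0168 with an estimated correlation), with Il1b at -7.03 ± 0.18 and Tnf at -5.12 ± 0.09. Chemokines gave 18 lower and 2 higher of 20 (adjusted p = 0.00604 with an estimated correlation), with Cxcl1 at -6.42 ± 0.24, Cxcl2 at -6.41 ± 0.12 and Ccl9 at -2.33 ± 0.05. Acod1 stood at 26.5 ± 3.19 CPM against 2767 ± 61.4 CPM (-6.71 ± 0.13). Clec4e (-6.21 ± 0.08), the anti-apoptotic gene Bcl2a1a (-6.33 ± 0.22), H2-M2 (-7.07 ± 0.22), Nlrp3 (-3.27 ± 0.05) and Icam1 (-3.42 ± 0.06) were likewise lower. Bcl2a1a has near-identical neighbours and H2-M2 belongs to a large family, so their reads could not be told apart with certainty. Interferon-stimulated genes were lower in 36 of 37 cases with none higher (median -1.25), by -2.21 ± 0.07 for Gbp2 and -1.13 ± 0.06 for Igtp (adjusted p = 0.274 with an estimated correlation). Adjusted over the list alone, the counts of these lists were the same.

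S-phase genes were higher in KO than in WT cells under ADP-Hep, 21 of 22 with none lower, the same adjusted over the list alone (adjusted p = 0.0195 with an estimated correlation), with Cdt1 at 1.5 ± 0.07, Mcm7 at 0.96 ± 0.06 and Rrm2 at 0.81 ± 0.05. Mertk (2.08 ± 0.06) and Gas6 (1.45 ± 0.05) were also higher, in a lysosome list of 14 higher and 6 lower of 25, the same adjusted over the list alone, which did not pass camera (adjusted p = 0.0573). The cholesterol list, higher in KO cells under PBS, gave 4 higher and 9 lower of 21 here (3 and 9 adjusted over the list alone) and a median of -0.02 (camera adjusted p = 0.300). Genes of the unfolded protein response gave 15 lower and 1 higher of 20, the same adjusted over the list alone, with Hspa5 at -0.85 ± 0.05 and Herpud1 at -1.33 ± 0.06 (adjusted p = 0.096 with an estimated correlation). Among single genes, Hpgd (3.94 ± 0.27), Frat2 (3.8 ± 0.20), Fam214a (3.5 ± 0.08), Abcd2 (3.25 ± 0.09) and Mtus1 (2.93 ± 0.06) were higher. Neutrophil markers moved with the lists that were lower: 9 of 11 were lower and 1 higher, the same adjusted over the list alone, Ngp by -0.75 ± 0.07 (adjusted p = 0.392 with an estimated correlation). With the preset correlation this list lay near the threshold (camera adjusted p = 0.0443). That call was lost with at least 1 CPM in 3 libraries (0.0501), thinning (0.0513) or all rows as deposited (0.0702). It was also lost without WT PBS replicate 3 (0.055) or KO PBS replicate 2 (0.0502). Cytosolic ribosomal protein genes, listed as a check of the samples, gave 12 lower and 0 higher of 22, the same adjusted over the list alone, with Rps2 at -0.24 ± 0.05 and Rpl8 at -0.19 ± 0.04. Camera called that list (adjusted p = 0.0285), but not with an estimated correlation (adjusted p = 0.565) or with library totals (adjusted p = 0.7235). Arg1 (-3.21 ± 0.17) and Cx3cr1 (-1.51 ± 0.05) were lower, as under PBS.

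In this comparison 4016 genes were higher and 3929 lower, 843 and 834 by at least 2-fold, and libraries did not overlap for 8408 of all genes tested (68.58%), against 10% by chance. Scaling by library totals, which put the median of all genes at 0.17 against 0.014, gave 5609 higher and 2722 lower, and glmTreat against 1.5-fold gave 1083 and 1121.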

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

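The tests of depth, of single libraries, of mixed RNA, of DNA near Alpk1, of culture handling and of the row shift were chosen after the results were seen, and the counts over other splits of the libraries were planned.

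The response to ADP-Hep differed between genotypes, by the interaction test, with 3018 genes positive and 3053 negative. The median interaction was 1.98 for NF-kB feedback genes, 2.10 for inflammatory cytokines, 3.27 for chemokines, 1.94 for nitric oxide, prostaglandin and itaconate enzymes with other effector genes and 1.01 for interferon-stimulated genes. It was 0.79 for immediate-early genes, 0.33 for pattern recognition receptors, 0.63 for inflammasome and cell death genes, 0.55 for antigen presentation, 1.28 for the tumour necrosis factor superfamily and 0.83 for matrix proteases. For metabolic and stress lists it was 0.37 for glycolysis, 0.55 for cholesterol, 0.34 for the unfolded protein response and 0.71 for NRF2 targets. The ALPK1 pathway list stood at 0.37, and S-phase and G2 and M phase genes at -0.49 and -0.24. With an estimated correlation the NF-kB, cytokine, chemokine, enzyme, inflammasome and S-phase lists passed, and the others named here did not (adjusted p from 0.0898 to 0.4435).

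Single genes with a positive interaction (log2) were Alpk1 at 0.89, Traf2 at 1.31, Ptgs2 at 8.51, Il1b at 7.59, Slc7a11 at 6.80, H2-M2 at 6.76, Adora2a at 6.30, Cxcl2 at 5.96, Clec4e at 5.83, Tnf at 4.63, Ccl3 at 3.30 and Ccl9 at 1.86. Further ones were Tnfaip2 at 2.89, Tnip3 at 3.15, Nfkbia at 2.96, Nlrp3 at 3.16, Sod2 at 3.06, Saa3 at 4.51, Icam1 at 3.26, Gbp2 at 2.24, Parp14 at 1.40, Junb at 2.07 and Fos at 2.60. Sqstm1 stood at 2.29 and Ppp1r15a at 3.07. Negative ones were Tifab at -1.23, Hpgd at -4.38, Abcd2 at -3.23, Rnf144b at -3.23, Cdt1 at -1.25, Mcm7 at -0.90 and Cdc6 at -1.53.

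Of 37 interferon-stimulated genes, 35 were higher after ADP-Hep in KO cells. There the NF-kB feedback list was not called by camera and was called lower by fry (adjusted p = 0.0132). Depth and single libraries are argued against, since 35 were higher with every library thinned to one depth and 33 or more with any 1 KO library left out, lowest without KO ADP-Hep replicate 1. RNA of treated WT cells in the KO ADP-Hep libraries would put both lists at the same share of the WT ADP-Hep level above KO PBS. Shares were taken over members called and at least 2-fold higher in the WT response. The median share was 0.194% over 15 NF-kB feedback genes (quartiles -2.29 to 1.35%). It was 24.8% over 33 interferon-stimulated genes (19 to 34.5%), which argues against mixing. An ALPK1-independent route, or another component of the agonist preparation, may underlie the response, and neither was tested.

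Of 21 cholesterol genes, 17 were higher in KO cells under PBS. A single library is argued against, since 16 or more were higher with any 1 PBS library left out. DNA near Alpk1 from another strain cannot be told apart from the genotype. Of the PBS calls 0.716% lay within 10 Mb of Alpk1, but the 56 genes tested there set a limit of 4.01%, so the share decides nothing. Handling of the KO PBS cultures cannot be told apart from the genotype either, since no batch is labelled. Under ADP-Hep the list median (log2) was -0.0234 between genotypes, with members going both ways. Whether ADP-Hep itself raised the list in WT cells, with 13 of 21 higher and 3 lower, depended on the test (camera adjusted p = 0.0138; adjusted p = 0.253 with an estimated correlation). An effect of the genotype on sterol genes stays open as a hypothesis.

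In the lower part of the table KO and WT values were unrelated as deposited. The KO columns held 56749 values for 56748 identifiers. Moving them up 1 row gave r = 0.975 across genes and at least 0.854 in each block wholly below the break. These values argue against a biological difference in those rows and for a shift of the KO columns. With the columns moved up, the rows not used held signal: in WT cells 200 genes were higher and 124 lower after ADP-Hep among 982 tested. Gbp5, an interferon-stimulated guanylate-binding protein in those rows, changed by 4.61 in WT cells.

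For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split called 7785 genes for the WT response, 3548 for the KO response, 1397 under PBS and 7945 under ADP-Hep, and the highest other split called 0 in each. For the interaction, 1 of 100 regroupings, the real one included, called as many as 6071 genes, and the highest other called 5148. Such splits of all 12 libraries break the effects of genotype and treatment along with the interaction, so they do not test the interaction by itself, and chance is not judged from them.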

How the results depend on the processing

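Thinning to a common depth and both treatments of the rows not used were chosen after the data were seen; the other alternatives were planned. No named gene or gene list changed direction with its call under any alternative run. The balance of call counts did shift with library totals, which gave 2360 higher and 1483 lower for the KO response against 1678 and 1870.

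Against a change of at least 1.5-fold (glmTreat), a stricter question by construction, calls fell to 1083 higher and 1055 lower for the WT response, 54 and 113 for the KO response, 820 and 706 for the interaction, 15 and 16 under PBS, and 1083 and 1121 under ADP-Hep. With all rows as deposited, shift included, 1632 were higher and 1518 lower under PBS, and 6 lists passed there. Leaving out each library in turn gave 438 to 772 higher and 391 to 793 lower under PBS, the lowest of both without KO PBS replicate 1 and the highest without WT ADP-Hep replicate 3; the cause was not tested. Other counts of calls stayed within 1.5 times of the main value.

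With an estimated inter-gene correlation, 6 lists passed for the WT response, 0 for KO, 6 for the interaction, 2 under PBS and 6 under ADP-Hep, against 17, 6, 18, 10 and 18 with the preset value. Fry, which asks only whether a list's genes move on balance one way, passed 33, 15, 29, 14 and 35 lists for the WT response, the KO response, the interaction, PBS and ADP-Hep. Under PBS fry did not call the interferon-stimulated list (adjusted p = 0.327), which camera with the preset correlation called lower (adjusted p = 0.0123). The correlation of WT and KO responses across genes ran from 0.184 to 0.282 with each library left out.

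Of 204 values of named genes, 44 lost their call with glmTreat. Apart from that, Rps2 and Rpl8 under ADP-Hep lost theirs with library totals. In the KO response Il10 lost it with DESeq2's Wald test, with the replicate block and without KO PBS replicate 2, Ikbkg with the block and without KO ADP-Hep replicate 1 or the unnumbered one, S100a9 with the block and Slc38a2 with only the groups compared. Under PBS, Slc7a11 lost its call without WT PBS replicate 1, 2 or 3, without KO PBS replicate 3 and with only the groups compared, and Ccl2 without KO PBS replicate 1. The cause was not tested.

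The replicate numbers did not pair the libraries: of 15 same-numbered pairs, 4 had a correlation of deviations over 0.1 (range -0.37 to 0.22), and 4 of 11 libraries were closest to their own number. A fit with the replicate block, without the unnumbered library, called 3847 higher and 3850 lower for the WT response, 1169 and 1414 for KO, 2782 and 2777 for the interaction, 633 and 594 under PBS and 3681 and 3627 under ADP-Hep. In simulations at this depth, with 3 libraries per group and 200 genes changed, small changes were missed most often. Of 1.2-fold changes in the WT response, among 12099 genes, 51% were recovered, and in the interaction 22.45%. The real WT response called 7785 genes and the interaction 6071. That moves the p cut-off of the adjustment, so the simulated shares do not give the recovery there.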

Other observations

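The counts of Ifnb1 and the level of Nnt were chosen after their values were seen. The test of genes within 10 Mb of Alpk1 was also chosen after the results were seen. The other values in these paragraphs come from the planned tests.

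Further genes changed in WT cells after ADP-Hep. The complement component C3 (3.11 ± 0.06) and the anaphylatoxin receptor C5ar1 (1.47 ± 0.05) rose in a complement and coagulation list of 8 higher and 4 lower of 14, the same adjusted over the list alone, which did not pass camera (adjusted p = 0.122). The membrane-bound protease gene Mmp14 (2.03 ± 0.05) and the gelatinase gene Mmp9 (2.66 ± 0.10) rose with 9 of 15 matrix genes higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.0542). The cytokine signalling inhibitor Socs3 rose by 5.32 ± 0.11 and the hypoxia-inducible factor gene Hif1a by 1.47 ± 0.05. The lipopolysaccharide co-receptor Cd14 (3.56 ± 0.08), the liver X receptor Nr1h3 (2.61 ± 0.08) and the cholesterol exporter Abca1 (1.48 ± 0.05) rose, while the iron exporter Slc40a1 (-1.96 ± 0.07), the nuclear receptor Pparg (-1.14 ± 0.08) and Apoe (-0.99 ± 0.04) fell.

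Between KO and WT cells under PBS, genes that can differ between C57BL/6 substrains were read as a check of the strain: Wdfy1 differed by -0.80 ± 0.06, Ide by 0.48 ± 0.05 and Cyfip2 by -0.25 ± 0.06. Nnt, which also differs between substrains, stood at 1.08 ± 0.253 CPM in WT and 1.40 ± 0.565 CPM in KO cells (0.37 ± 0.33, adjusted p = 0.541). The labels name C57BL/6N and the design text C57BL/6, so the substrain of each genotype is not settled here. Of genes beside Alpk1 on chromosome 3, Sec24d differed by -0.39 ± 0.05 and Camk2d by -0.35 ± 0.05. Of genes tested within 10 Mb of Alpk1, 10 of 56 were called (17.9%), against 11.4% of other genes (Fisher's exact test, two-sided p = 0.137). The NRF2 target Gclm was among the 10 called.

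Ifnb1, encoding interferon beta, lay under the expression filter. It had 0, 1 and 0 counts in the WT PBS libraries, 3, 5 and 6 in the WT ADP-Hep libraries and 0 in each of the 6 KO libraries.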
